A study of Clostridium acetobutylicum with 11 samples.

How the data were processed

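The series compared a strain of Clostridium acetobutylicum, a solvent-forming and spore-forming anaerobe, that carries a plasmid with an antisense RNA against CAC0654 with a strain carrying the control plasmid pSOS95del. Both cultures were grown in a bioreactor, and 6 pairs of samples, named A to F, were taken along the fermentation. Each pair was hybridized on 2-colour spotted arrays, once with the antisense strain in Cy5 (replicate 1) and once with the dyes exchanged (replicate 2). Time point B has 1 array, since the series text states that the other slide was discarded for high deviations, so 11 arrays were analysed.

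The labels disagree on 2 points. The sample labels pair each antisense sample with a control sample of its own time, whereas the series text describes 1 control made by combining all control times. The series text also places the antisense samples between 9 and 19 h, whereas the sample labels give 10.5 to 20.5 h; the sample labels were used. A single culture per strain is described, so p-values measure the spread between time points and not between cultures.

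The deposited scanner files hold spot intensity and local background values per channel, exported by GenePix Pro 5.0.0.49 without normalization, per the file headers. The deposited files also give, per the file headers, the percent of saturated pixels of a spot and a flag score that marks spots as bad or not found. The authors' series table holds 1 value per spot, read here as the natural log of Cy5 over Cy3. It correlated with the ratio of the same spot in the scanner files, corrected and normalized as described below, on all 11 arrays. Across the brighter unflagged spots r was 0.932 to 0.991, and column medians lay between -0.05 and 0.09. Over those brighter spots its spread was 0.728 to 0.970 times that of the log2 ratios, against 0.693 for a natural log, so its scale stays unsettled. Its normalization is not given in the sources used here. The direction, Cy5 over Cy3, was borne out.

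Intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50, and log ratios were normalized within each array by loess with a span of 0.3, with flagged and control spots at weight 0. Spots flagged as bad or not found were left out. Genes were kept where at least 50% of their spots exceeded the local background by 2 background SD in either channel on at least 50% of the arrays. The array holds 13056 spots and 3 spots per gene probe name. Probe names give 3802 locus tags, of which 3412 passed the filter and 3375 had a value at all 6 time points. Ratios of all spots and probes of a locus were averaged; among 214 loci with several comparable probes, 2 had probes more than 1 log2 unit apart and 0 had probes of opposite sign beyond 0.5. Every ratio was turned to antisense strain over control, and both arrays of a dye swap were averaged to 1 value per time point, since they hold the same pair of extracts.

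The strain difference was the mean log2 ratio over 6 time points against 0 (lmFit and eBayes, two-sided, Benjamini-Hochberg at 0.05), and the time trend was the slope per hour of growth of the antisense strain. CAC0654 was tested by an exact sign-flip permutation test. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation; where an alternative changed the model, cameraPR was run on the statistics of that model. Separate-channel values were obtained after equalizing mean log intensities between arrays by quantiles.

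On data simulated from the spread of the 3375 genes, with 200 genes changed, the strain-difference test found 156 of the 200 at a log2 change of 1 and 197 at 2, with 9 false calls each. The trend test found 0 of 200 at a change of 1 over the course and 108 at 2, with 7 false calls. Simulated values were independent between time points, whereas the real time points correlated within a scan session (0.355). These rates therefore hold for independent time points only. A planted ratio came back with the right sign on 11 of 11 arrays.

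The share of gene spots above background ran from 68.5% (time point C, replicate 1) to 91.0% (time point D, replicate 2). Flagged gene spots made up 4.74% to 26.4%, the latter on the replicate 1 array of time point C. Precision is limited by the number of time points and the single culture per strain, since the arrays of a pair hold the same extracts. Image names in the headers placed the arrays in 3 scan sessions, holding time points A and B, C and D, and E and F.

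Genes are named by the locus tags of the array, and positions are not given, since no annotation was used here. Gene symbols and functions are background knowledge. Before the data were examined, 13 lists of loci and the rule for named genes were fixed; 11 further lists defined by product text could not be applied without an annotation. In their place 12 lists of loci were written before gene values were looked at, and 3 chromosomal regions were chosen after gene values were seen. Named genes were CAC0654; the 10 largest rises and 10 largest falls past an adjusted p of 0.05 with 1 sign at all time points, or, where none passed, the 5 largest changes; 9 preset sporulation and solvent genes; and up to 4 members of each list described. Alternatives covered background correction, normalization, filters, probe averaging, the authors' table, the replicate block, left-out replicates and time points, covariates, the variance model and scan session; further ones were added after the data were seen. Figures were drawn with matplotlib 3.10.9.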

Results

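RNA of the antisense strain and of the plasmid control strain was compared on 11 arrays at 6 time points along a fermentation, A to F, which the sample labels place at 10.5, 13.5, 15, 16.5, 18.5 and 20.5 h for the antisense strain and at 9, 12, 13.5, 15, 16.5 and 19.5 h for the control. Optical density ran from 1.09 to 6.58 in the antisense culture and from 1.23 to 5.88 in the control culture. The pairs, antisense then control, were 1.09 and 1.23 at A, 3.94 and 3.74 at B, and 5.14 and 4.70 at C. They were 6.08 and 4.90 at D, 6.58 and 5.34 at E, and 6.05 and 5.88 at F. The paired cultures thus differed most in density at D and E, and whether this contributed to the ratios there was not tested. Values are log2 ratios of the antisense strain over the control, positive where the antisense strain was brighter, with 1 value per time point (n = 6). A single culture per strain is described, so no value carries an error between cultures.

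The first question was whether the targeted gene, CAC0654, was lowered. The spot of this gene gave no lower signal in the antisense strain: its mean log2 ratio was 0.27 ± 0.43 (SD, n = 6; 95% confidence interval -0.19 to 0.72), and an exact two-sided sign-flip permutation test gave p = 0.156, where 0.0313 is the smallest p that 64 sign assignments allow. The ratio was 0.00 at A, above 0 from B to E, up to 0.90 at D, and -0.35 at F. The arrays gave 0.80 and 1.00 at D. At F the replicate 2 array gave -0.40 from 3 spots and the replicate 1 array -0.30 from the 1 spot left unflagged. With 1 of 3 spots left, the replicate 1 array could not count as above background, whatever its signal. The value below 0 at F thus rests on 1 full array and 1 spot of the other. At E on replicate 1, with 3 spots, neither channel was above background. The labelled cDNA was primed with random hexamers, and the strand of the probe is not given in the sources used here. The spot may read the transcript, the antisense RNA or both, and it does not check the strain labels.

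**Figure D1:**
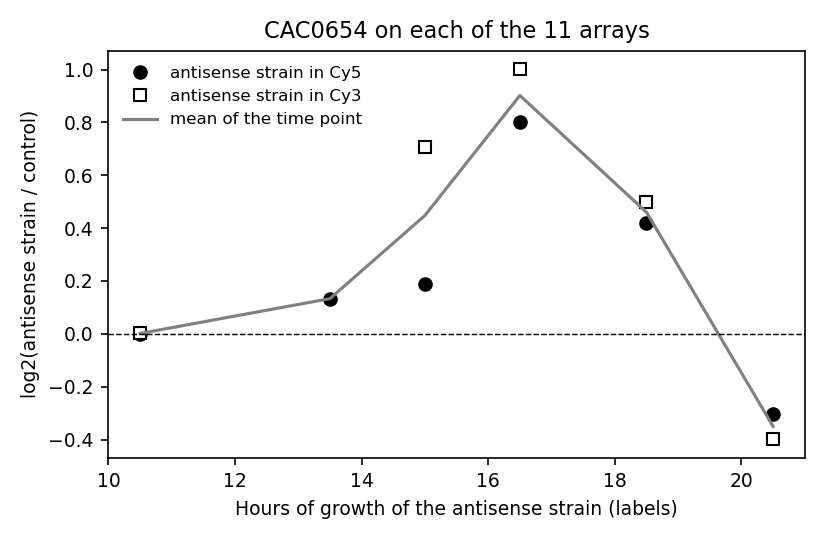
Log2 ratio of CAC0654 (antisense strain over control, vertical axis) on each of the 11 arrays against hours of growth of the antisense strain. Filled circles have the antisense strain in Cy5, open squares in Cy3, and the line joins the means of the time points; the mean is highest at D (0.90) and below 0 at F (-0.35).

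Of 12 early sporulation regulators, 8 rose and 4 did not pass (11 rose when adjusted over the list alone), with a median log2 ratio of 1.11 (camera adjusted p = 1.34e-06; adjusted p = 0.308 with an estimated correlation). CAC2859 (spoIIID, a regulator of the mother cell) rose the most of all genes named by the rule, by 2.69 ± 1.62 (SD, n = 6; 6.46-fold; limma adjusted p = 0.0375). The sporulation sigma factor genes sigE (CAC1695), sigK (CAC1689), sigG (CAC1696) and sigF (CAC2306) rose by 1.53 ± 1.06, 1.52 ± 0.81, 1.43 ± 0.77 and 1.15 ± 0.50, with limma adjusted p of 0.0446, 0.0344, 0.0344 and 0.0235, each higher at 6 of 6 time points; the control channel of sigK was above background on 9 of 11 arrays, so its size is less certain. CAC2898 (spoIIR) rose by 1.46 ± 0.99 (limma adjusted p = 0.0445). spo0A (CAC2071), the master regulator of sporulation, had a mean of 0.45 ± 0.47 and did not pass (limma adjusted p = 0.131). CAC3152 (sigH) had a mean of -0.10 and was lower at 4 of 6 time points. The list median was 0.33 at A, 1.40 at B, 1.63 at C, 1.60 at D, 1.11 at E and 0.39 at F.

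Of 12 genes of the spoIIIA operon and other sporulation loci, 2 rose, CAC2086 by 2.61 ± 1.71 and CAC2087 by 2.51 ± 1.77 (limma adjusted p = 0.0415 and 0.0446), and 10 did not pass (11 rose when adjusted over the list alone; median 1.26; camera adjusted p = 1.32e-05; adjusted p = 0.308 with an estimated correlation). CAC2090 and CAC2093 had means of 2.35 and 2.33 (limma adjusted p = 0.0532 and 0.0544). In the granulose list, storage polysaccharide synthesis, 2 of 3 measured genes rose, CAC2237 by 1.78 ± 1.10 and CAC2238 by 1.78 ± 1.10 (limma adjusted p = 0.0389 each; 3 adjusted over the list alone); CAC2240 had a mean of 1.85 and did not pass (0.0566). The list median reached 3.39 at D (camera adjusted p = 0.00763; adjusted p = 0.308 with an estimated correlation). Other large rises were CAC2858 (2.29 ± 1.51), CAC0989 (2.06 ± 1.17), CAC1697 (2.01 ± 1.23), CAC2575 (1.96 ± 0.72), CAC1713 (1.95 ± 1.17), CAC2791 (1.89 ± 1.34) and CAC2625 (1.82 ± 1.24), with limma adjusted p from 0.0116 to 0.0463. The control channel of CAC1697 and CAC2625 was above background on 8 of 11 arrays and that of CAC2791 on 10, so the sizes of these rises are less certain.

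**Figure D2:**
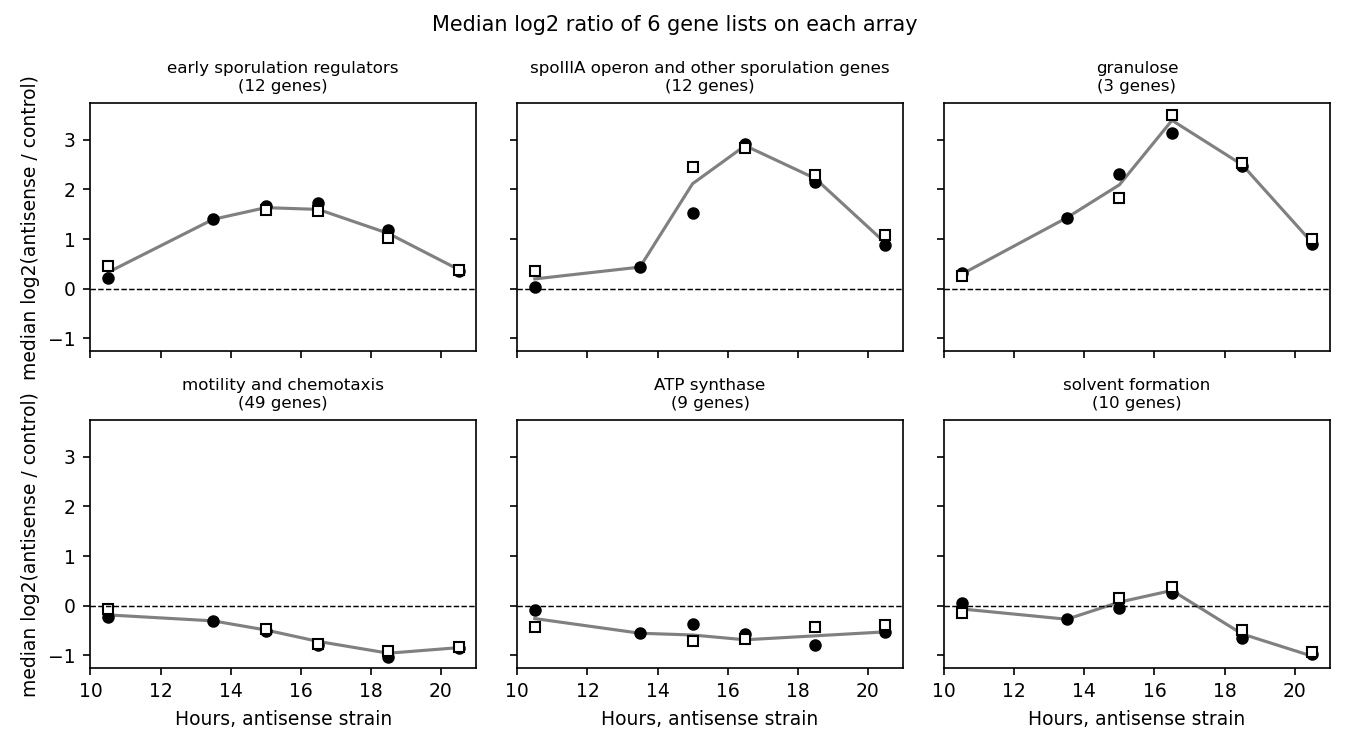
Median log2 ratio (antisense strain over control, vertical axis) of 6 gene lists against hours of growth of the antisense strain. Filled circles are replicate 1 arrays, open squares replicate 2 arrays and lines join the medians of the time-point means; early sporulation regulators peak at C (1.63), the granulose list at D (3.39), and motility and chemotaxis is lowest at E (-0.96).

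The 3 largest falls were in a run of neighbouring loci around the kdp potassium uptake genes, CAC3681, CAC3682 and CAC3680. CAC3681 fell by 2.70 ± 0.50 (SD, n = 6; 6.52-fold; limma adjusted p = 0.000818), CAC3682 fell by 2.57 ± 0.66, CAC3680 fell by 2.36 ± 0.51 and CAC3679 of the same run fell by 2.00 ± 0.52, each lower at 6 of 6 time points. CAC1134, CAC1138, CAC1124 and CAC1132, which lie close together on the chromosome, had mean log2 ratios of -2.11, -1.90, -1.69 and -1.59, and CAC1001 and CAC0778 of -1.88 and -1.61; all passed. In the antisense channel CAC1124 and CAC1001 were above background on 3 of 11 arrays, CAC1138 on 4, CAC1132 on 5, CAC1134 on 7, CAC3679 on 8, CAC3680 and CAC0778 on 9, and CAC3681 and CAC3682 on 10. The sizes of these falls and their order are uncertain to that extent.

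Motility and chemotaxis genes were lower as well. Of 49 measured, 20 fell and 29 did not pass (44 fell when adjusted over the list alone), with a median of -0.63 (camera adjusted p = 2.16e-18; adjusted p = 0.308 with an estimated correlation). CAC2209 fell by 1.05 ± 0.52, CAC2162 fell by 0.97 ± 0.61, CAC2213 fell by 0.91 ± 0.52 and CAC2164 fell by 0.89 ± 0.59, with limma adjusted p from 0.0344 to 0.0461. Of 9 ATP synthase genes, 7 fell (8 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 1.15e-05; adjusted p = 0.308 with an estimated correlation); CAC2870 fell by 0.70 ± 0.15 and CAC2871 fell by 0.59 ± 0.16. In the butyryl-CoA pathway 3 of 7 genes fell (5 adjusted over the list alone), namely CAP0078 (thlB, thiolase) by 0.94 ± 0.59, CAC2873 (thlA, thiolase) by 0.57 ± 0.31 and CAC2709 (an electron transfer flavoprotein gene) by 0.43 ± 0.13. Its median was -0.43 (camera adjusted p = 0.00103; adjusted p = 0.308 with an estimated correlation).

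Of the acid formation list, 2 of 5 genes fell (2 adjusted over the list alone), CAC3076 (ptb) by 0.76 ± 0.40 and CAC3075 (buk) by 0.72 ± 0.23, while CAC1743 (ack), CAC1742 (pta) and CAC1660 (a second butyrate kinase gene) had means of -0.17, -0.15 and -0.10 and did not pass. Its median was -0.17 (camera adjusted p = 0.0314; adjusted p = 0.308 with an estimated correlation). In the heat shock and chaperone list 4 of 15 fell, CAC3192, CAC3190 and CAC3191 of one operon by 0.74, 0.70 and 0.63 and CAC3315 by 0.66; the median was -0.26 (camera adjusted p = 0.0135; adjusted p = 0.308 with an estimated correlation). Of 7 phosphate uptake genes 2 rose (2 adjusted over the list alone), CAC1708 by 0.77 ± 0.50 and CAC1709 by 0.68 ± 0.37 (control channel above background on 10 and 7 of 11 arrays), with a median of 0.33 (camera adjusted p = 0.00329; adjusted p = 0.308 with an estimated correlation). The histidine synthesis list had a median of 0.22 with 0 of 7 genes past the threshold (camera adjusted p = 0.0420; adjusted p = 0.329 with an estimated correlation).

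In the solvent formation list 1 of 10 genes fell (1 adjusted over the list alone), CAC3299 (bdhA, butanol dehydrogenase) by 0.72 ± 0.39 (limma adjusted p = 0.0402), and the list did not pass (median -0.24; camera adjusted p = 0.323). The genes of the sol locus, adhE1 (CAP0162), ctfA (CAP0163), ctfB (CAP0164) and adc (CAP0165), had means of -0.64, -0.58, -0.44 and -0.27 and did not pass (limma adjusted p = 0.242, 0.282, 0.335 and 0.383). Their lowest values were at F, at -2.49, -2.41, -1.98 and -1.24. Of 163 loci of the pSOL1 megaplasmid, which can be lost in culture, 4 fell and 0 rose (0 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.813). The 4 were CAP0078, CAP0012, CAP0077 and CAP0041, with means of -0.94, -0.75, -0.69 and -0.47.

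The remaining lists did not pass with camera, and 0 of their genes passed over all genes; adjusted over the list alone, 0 passed as well, except both measured genes for small acid-soluble spore proteins. Median log2 ratios were 0.09 for the 7 measured neighbours of CAC0654 (adjusted p = 0.875), -0.17 for glycolysis (0.174), -0.43 for the agr system (0.188), -0.03 for the cellulosome cluster (0.883), -0.29 for sulfur assimilation (0.522), 0.49 for small acid-soluble spore proteins (0.113) and 0.07 for a ribosomal protein cluster (0.519). They were -0.29 for purine synthesis (0.119), 0.19 for arginine synthesis (0.879), -0.06 for tryptophan synthesis (0.709), -0.03 for orphan histidine kinases (0.879), -0.33 for cell division and shape (0.323) and 0.06 for sugar phosphotransferase systems (0.875), where camera's direction was down. The values of 2 lists depend strongly on 1 time point. Sulfur assimilation was at -2.13 at C and between -0.10 and 0.50 otherwise. Arginine synthesis was at -4.49 at D and between 0.20 and 2.43 otherwise.

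Over all 3375 genes, 233 passed at an adjusted p of 0.05 (limma), 90 higher and 143 lower in the antisense strain, of which 45 and 38 differed by at least 2-fold. Of the 233, 223 had 1 sign at all 6 time points. That largely follows from the test, which sets the mean of these 6 values against their spread. Over all genes tested, 679 (20.1%) had 1 sign at all 6, where independent signs would give 3.13%. With scan session as a random block 25 genes passed, 3 higher and 22 lower. Of the genes named above, CAC2575, CAC3679 to CAC3682, CAC1134, CAC1138, CAC1124, CAC1001, CAC0778, CAC2870 and CAC3192 were among them, and none of the sporulation, granulose, motility, butyryl-CoA, acid, solvent or phosphate genes. The count was 511 without A, 25 without B, 12 without C, 10 without D, 18 without E and 46 without F, 13 (all lower) with a trended, robust variance, 619 with the replicate block (364 higher, 255 lower), and 14 for the antisense channel against the control channel of the same labelled hours (3 pairs).

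Within the scan sessions of A and B, C and D, and E and F, early sporulation regulators had medians of 0.93, 1.52 and 0.72, the spoIIIA list 0.26, 2.37 and 1.65, the granulose list 0.89, 2.74 and 1.71, motility genes -0.28, -0.57 and -0.96, and ATP synthase genes -0.37, -0.65 and -0.61. Within those sessions, of 2 time points each, 0, 493 and 0 genes passed.

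No gene passed for a trend of the ratio with time (limma; 0 of 3375, 454 at an unadjusted p under 0.05, 182 with a rising and 272 with a falling ratio; smallest adjusted p 0.0852). A straight line captures poorly a ratio that rises and falls again, so this result does not mean that ratios stayed constant. CAC2859, for example, was at 0.45 at A, 4.45 at D and 2.25 at F (limma slope adjusted p = 0.506). The largest slopes that kept their sign without any 1 time point did not pass. Upward they were CAC0623 (0.43 per hour), CAC2059 (0.36), CAP0067 (0.34), CAC2925 (0.34) and CAC2428 (0.33), and downward CAC1361 (-0.42), CAC1360 (-0.40), CAC2695 (-0.37), CAC2015 (-0.33) and CAC1362 (-0.32). CAC2059 and CAC2428 were above background in the control channel on 7 of 11 arrays and in the antisense channel on 9, so their slopes are less certain. Among lists, motility and chemotaxis alone passed (median slope -0.09 per hour; camera adjusted p = 1.23e-12; adjusted p = 0.599 with an estimated correlation), with medians of -0.19 at A and -0.85 at F. Its members' slopes passed for 0 of 49 over all genes and 10 when adjusted over the list alone. The number of lists was 4 without A, 2 without B, 2 without C, 2 without D and 6 without F.

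The number of genes at least 2-fold apart in 1 direction on both arrays of a dye swap, a description of size with no test, was smallest at A and largest at E. It was 98 at A (45 higher, 53 lower), 239 at C (193, 46), 495 at D (344, 151), 593 at E (377, 216) and 272 at F (117, 155). Genes 2-fold apart in opposite directions on the pair of arrays numbered 0, 10, 2, 2 and 30. At B, on its 1 array, 96 were higher and 100 lower. Across genes, which are not independent replicates, the dye-swapped arrays correlated with r of 0.574, 0.848, 0.920, 0.946 and 0.807.

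The control channel differed between time points. Its median for the early sporulation regulators was 8.45, 10.08, 10.18, 10.47, 11.04 and 11.58 log2 units from A to F, against 8.90, 11.98, 12.57, 12.13, 12.24 and 11.99 in the antisense channel. Over 3375 genes the median SD over time of the control channel was 0.493, against 0.179 for the scaled difference between the arrays of a dye swap, and 1121 genes differed at least 2-fold in the control channel between A and the mean of D to F. These 2 measures of spread are not alike, an SD and a median absolute difference. The arrays of a pair also share a scan session, so the pair difference leaves out session effects. The 2 channels' changes correlated across genes with r = 0.828, part of which array effects shared by both channels could give.

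**Figure D3:**
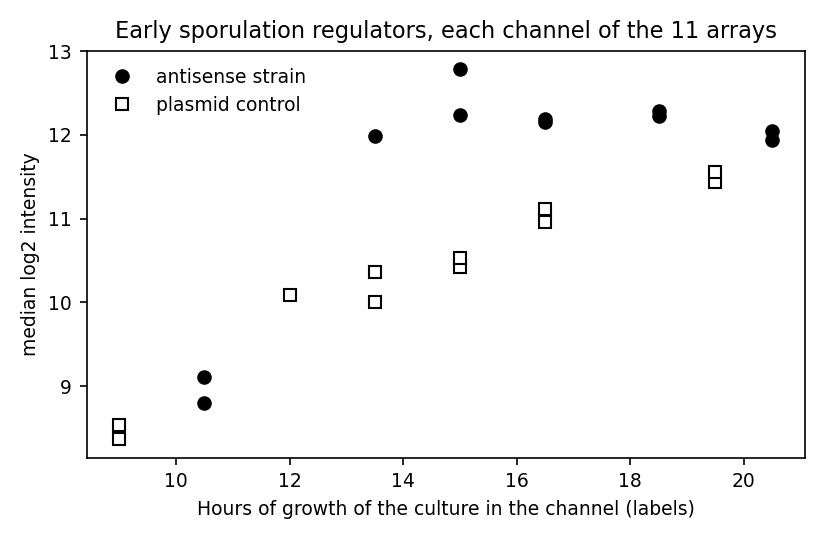
Median log2 intensity (vertical axis) of the 12 early sporulation regulators in the antisense channel (filled circles) and the control channel (open squares) of the 11 arrays, against the labelled hours of growth of the culture in that channel. The control channel goes from 8.45 at A to 11.58 at F, as medians of the time-point means.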

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

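The dye-orientation, same-hours, pooled-control and single-time-point tests below were chosen only after the results were seen; the print-block test and the counts over other splits were set before their results were seen.

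The values of 100 named genes and list medians over the 6 time points were searched for a time point far from the rest. 5 were found, and chance gives about 5% of groups, or 5 here. Sulfur assimilation had a median of -2.13 at C, with the other time points between -0.10 and 0.50. Arginine synthesis had -4.49 at D, with the others between 0.20 and 2.43. The agr system had 0.92 at A, with none of the others above -0.59. ATP synthase had -0.26 at A, with the others between -0.69 and -0.53. CAC3191 had -0.24 at C, with the others between -0.88 and -0.64.

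Some values moved in opposite directions at different time points on both arrays of each, a difference that was not tested. CAC1361 was at 4.22 at C and -2.28 at F, CAC1360 at 4.47 and -1.94, and CAC1362 at 4.60 and -1.95. The antisense sample at C and the control sample at D carry the same labelled hours, 15. Their channels were at 14.35 and 15.37 for CAC1361, 14.53 and 14.97 for CAC1360, and 13.87 and 14.00 for CAC1362. The excess at C was thus absent at the same labelled hours, between channels of different arrays. Under the series-text hours these 2 samples are not matched. CAC2015 was at 1.31 at A and -2.25 at F. CAP0067 was at -1.50 at A and 3.09 at E. Arginine synthesis, as the mean of the array medians, was at -4.42 at D and 2.37 at E.

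Among spots that carry no locus and entered no comparison, 0.0473% of the measurements of blank spots were above background. The families named Alien, IG, MOP and Past were above background in 85.0%, 87.5%, 12.3% and 20.0% of measurements. What these families hold is not given in the sources used here.

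The 233 genes that passed for the strain difference were not matched by any other of the 32 sign assignments of the 6 time points. Only 1 of 32, the real one, gave as many, and the highest other, with A alone turned, gave 19. This count would exclude chance only if signs were independent between time points, so it does not decide the question for these data. The time points are not independent: they come from 1 culture per strain and 3 scan sessions (correlation within a session 0.355), and 25 genes passed with scan session as a block. For the time trend, 11 of 100 drawn time orders gave at least the 454 genes at an unadjusted p under 0.05, the highest other giving 894, so chance cannot be excluded.

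The list median of the early sporulation regulators was above 0 at all 6 time points, while 4 of the 12 genes did not pass and CAC3152 had a mean of -0.10. Dye bias is argued against by medians of 1 sign on both arrays at 5 of 5 dye-swapped time points, and a single pooled control by a control channel 3.04 higher at F than at A (means of array medians), against at most 0.353 between the arrays of a pair. The arrays of a pair share a scan session, and those of A and F do not. Within the session of A and B the control channel went from 8.45 to 10.08, the latter on 1 array. The later labelled sampling of the antisense strain is argued against as the whole cause. Against the control channel of the same labelled hours the median was 1.29 ± 0.17 (SE over 3 pairs). Against the paired control it was 1.54 at the same antisense time points. The 3 pairs come from 1 culture per strain and set channels of different arrays, in part of different scan sessions, against each other. Their SE thus measures no error between cultures. Under the series-text hours (9 to 19 h) the paired control, at 9 to 19.5 h, is already nearly matched in hours. With scan session as a block (3 genes higher in all) the regulators' single-gene calls were lost at the same estimates, with larger errors and with the adjustment over fewer passing genes, as for sigF (CAC2306) at 1.15 ± 0.18 (SE) without and 1.15 ± 0.23 with the block (limma adjusted p = 0.0235 and 0.0790). A difference between cultures unrelated to the antisense RNA stays open, as does the effect of the antisense RNA, since a single culture per strain is described and the CAC0654 spot may read the antisense RNA as well as the transcript.

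The 2 prophage-like regions, CAC1113 to CAC1197 and CAC1878 to CAC1957, and the kdp region, CAC3677 to CAC3684, were chosen after their values were seen; 26 of 51, 14 of 52 and 6 of 8 measured loci fell, with medians of -0.57, -0.35 and -1.62. Dye bias is argued against by medians of 1 sign on both arrays at 5 of 5 dye-swapped time points. The called loci's spots lay in 48 of the 48 print blocks. That count takes in every spot of a called locus, low or not, and so largely follows from the array layout. It cannot decide whether a damaged part of the slide contributed. Of the named ones, CAC1138 and CAC1124 were above background in the antisense channel on 4 and 3 of 11 arrays, and cross-hybridization between related phage genes was not tested. The medians at A were already -0.80, -0.33 and -0.99, so a difference between the strains or inocula that predates the time course may contribute as well as the antisense RNA, and neither was tested.

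The low arginine synthesis ratio at D and the low sulfur assimilation ratio at C each appeared at a single time point. Failure of 1 array is argued against, since all 4 arrays concerned had list medians under -1 (-4.38 and -4.46 for arginine, -2.09 and -2.19 for sulfur). A step of the antisense extract alone is argued against: the control channel departed from the median of its other times by 4.90 for arginine and 5.03 for sulfur and the antisense channel by -0.75 and 2.99, at least 2.04 less. For sulfur both channels were higher. A transient of the control culture or its sample may therefore set these ratios, and no biological explanation was tested.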

How the results depend on the processing

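The settings with left-out single arrays, kept spots, within-session fits, same-hours pairs and gene-list values beyond the planned ones were chosen after seeing the data. Of 2925 alternative values, 2240 were labelled the same. For ratios and medians this meant the same direction and side of the threshold, and for counts a similar size, such as 345 genes with scale normalization for 233. A further 473 lost and 62 gained the threshold. Another 147 moved, as counts that changed more or values that changed sign without passing. The other 3 reversed, a change of sign with a pass in the main or the alternative setting. All 523 values of the 20 genes named for the strain difference kept their sign, and 134 lost the threshold, 99 of them rises and 35 falls. Kept signs are in part fixed by the rule, since these genes were named for 1 sign at all 6 time points. Means over fewer time points therefore could not change sign. The hours covariate, the trended, robust variance and the session block left the estimates as they were. CAC0654 stayed above 0, from 0.05 to 1.07, and did not pass in any setting, though exact tests on fewer than 6 time points could not reach 0.05. For the 233 genes of the strain difference, the count was 111 without background correction, 370 with plain subtraction, 121 for genes above background in both channels of all arrays, 525 with hours as a covariate and 13 (all lower) with a trended, robust variance. It was 25 with scan session as a block, 14 with same-hours control pairs, and 0, 493 and 0 within the sessions of A and B, C and D, and E and F (2 time points each). It ranged from 10 to 511 with 1 time point left out: 511 without A, 25 without B, 12 without C, 10 without D, 18 without E and 46 without F. The replicate block, which keeps 11 arrays of 6 extract pairs with a dye term, gave 619 genes for the strain difference, 53 for the time trend and 4 lists for the trend; replicate numbers mark dye orientation of the same extracts, so they pair no cultures. The share of calls that were higher, 38.6%, was not stable. It was 0% without C, without D and with the trended, robust variance, 11.1% without E, 12.0% with scan session as a block, 19.6% without F, 28.0% without B and 30.6% without background correction. It was 50.0% with plain subtraction, 50.8% with the authors' ratios, 51.9% without A, 58.8% with the replicate block, 64.7% without replicate 1, 71.4% with same-hours pairs and 71.6% within C and D. The time trend's 0 became 1 with the both-channel filter, 1 with the authors' ratios, 1 with median centring and 9 with log2 OD. The 10 lists of the strain difference became 0 with an estimated correlation. The single list of the trend became 0 with an estimated correlation, 2 with the both-channel filter, 5 with log2 OD, 5 with median centring and 7 with scan session as a block, and ranged from 1 to 6 with 1 time point left out and from 2 to 7 with 1 replicate left out. At 3-fold the counts from A to F were 23, 75, 113, 245, 247 and 84, and without background correction F had 163 in place of 272. Reversed medians were -0.12 for pSOL1 (same-hours pairs), -0.29 for the ribosomal cluster (C and D) and -0.84 for sugar phosphotransferase systems (A and B). Apart from smaller sets of time points, the cause was not tested. Signal over background, a median of 1.83-fold in Cy5 at F replicate 1 and 1.76-fold in Cy3 at C replicate 1, limits dim genes.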

Other observations

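Both tests in this part were chosen after related values had been seen. Channel values over time carry no test here. Purine synthesis genes had lower medians late in both strains: the control channel of 6 genes went from 12.47 at A to 8.87 at F and the antisense channel from 12.13 to 8.65, while their ratio did not pass. Solvent formation genes went from 10.24 to 13.69 in the control channel and from 10.30 to 12.82 in the antisense channel, with 14.42 at D. Across genes, which are not independent replicates, ratios at A correlated weakly with those at later time points (r from 0.04 to 0.23), while C and D correlated with r = 0.710 and D and E with r = 0.702.

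Genes that passed in 1 direction lay side by side on the chromosome. Neighbouring locus numbers passed in the same direction 74 times, 56 lower and 18 higher, against a median of 7 and at most 19 in 10000 shuffles (permutation p = 1e-04, the smallest these shuffles can give). Bacterial operons place co-transcribed genes side by side, so this is consistent with operon-sized units of change and does not separate causes. The longest runs were CAC2866 to CAC2873 (8 loci, lower), which spans ATP synthase genes and thlA, and CAC3677 to CAC3682 (6 loci, lower).

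A hypothesis that the whole antisense culture ran ahead of the control was tested by the distance between channel profiles. The 24 sporulation genes of the antisense strain at C, D and E lay nearest to the control at F, and at B nearest to the control at B. Their distances to the control at F were 0.98, 1.46 and 1.43, so nearest does not mean alike. Antisense medians of the early sporulation regulators at C, D and E (12.57, 12.13 and 12.24) were above every control median, the highest being 11.58 at F. For genes higher in the antisense strain and rising in the control, the last control is likely to be nearest. The 3348 genes outside the sporulation and granulose lists lay nearest to the control of the same time point at 2 of the 4 time points B to E, namely B and C, while D lay nearest to E and E to F. The result therefore leaves open whether a general shift adds to the sporulation difference at D and E: the control at E carries the same labelled hours, 16.5, as the antisense sample at D.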
